A study of Homo sapiens with 6 samples.

How the data were processed

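Gene expression was measured on 6 2-colour spotted arrays with RNA from Jurkat cells, a human T-cell leukaemia line. Per the labels, each array carried Cy5-labelled RNA from cells given siRNA against p65 or RPS3, and Cy3-labelled RNA from cells given nonspecific control siRNA. Both samples of an array came from cells stimulated for the same time, 1, 3 or 6 h, by anti-CD3/CD28 at 1 ug. The labels describe Trizol extraction and reverse transcription primed with oligo-dT. They name no dye swap and no array of control against control, and each siRNA had 1 array per time.

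The deposited values were log ratios of the 2 channels per probe, here read as log2. The log base was not given in the sources used here: base 10 was excluded because values reached 9.52, and a natural log was not, in which case every size printed would be larger on the log2 scale. Image analysis, background correction, the rule behind blank cells and the normalization were not given in the sources used here. The deposited medians lay between -0.019 and 0.007 on the 6 arrays, so the values had been centred before deposit. The direction was taken as siRNA over control, as is usual for Cy5 over Cy3. It is called likely rather than settled, because the deposited values state no direction. Its basis besides the dyes is the RPS3 probe, which lay at -1.44 or below on the RPS3 siRNA arrays and at 0.01 or above on the p65 siRNA arrays, so that probe is no independent check of the labels of the channels. Channel intensities were not used here, so signal over background is unknown, and the number of arrays limits the precision.

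The table held 15246 probes. The platform annotation gave 1 gene symbol for 10169 probes (4604 symbols), several symbols for 4 and none for 5073; probes without 1 symbol stayed single and unnamed. Of the probes with 1 symbol, 10128 matched a current gene record, and none changed its symbol (0 changes). Blank cells made up 5.40% to 15.1% of an array. Each array was centred on its median, and probes of 1 symbol were averaged on each array. Of 3932 tested genes, 1276 had at least 1 probe with a blank, so the probes averaged differ between arrays, and 78 had no probe with values on all 6 arrays. The 7267 features with a value on all 6 arrays were tested, 3932 with a symbol and 3335 unnamed probes.

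Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 6 arrays, with the 3 times of a siRNA standing as its replicates. The mean of each siRNA's arrays was tested against 0, as were the difference (RPS3 siRNA minus p65 siRNA), the mean of all 6 arrays, and the slope of the log2 ratio per hour of stimulation with both siRNAs in the fit. Benjamini-Hochberg adjusted p-values under 0.05 counted as passing. A test of a ratio against 0 leaves out the control's own spread, and a dye effect common to all arrays stays in it; such an effect cancels in the difference. Nothing in the labels says that the arrays came from separate cultures, so p-values measure only the spread between these arrays, which can be technical, and times differ among the arrays of a group. ID numbers in the labels fall into 2 consecutive series, read here as array runs: run 1 held the p65 1 h and RPS3 3 h arrays, and run 2 the other 4.

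Before the data were examined, 23 gene lists were fixed: NF-kB and IkB family, NF-kB target genes, immediate-early activation genes, T cell cytokines and activation markers, T cell receptor complex and signalling, interferon-stimulated genes, apoptosis regulators, p53 target genes, G2 and M phase, S phase and DNA replication, small ribosomal subunit proteins without RPS3, large ribosomal subunit proteins, ribosome assembly and nucleolus, translation factors, unfolded protein and amino acid stress response, heat shock proteins, proteasome, oxidative phosphorylation, glycolysis and hypoxia, cholesterol and fatty acid synthesis, RNA interference machinery, reference genes, and markers of other cell lineages. They held 829 symbols, of which 465 were on the array and 436 were tested. Some lists were tested only in part: 11 of 47 large and 13 of 31 small ribosomal subunit proteins, and 16 of 72 oxidative phosphorylation genes. Each list was compared with all other features by camera of limma, with a preset correlation between genes of 0.01 and adjustment over the 23 lists of a contrast. The slope over time was added to the contrasts of the lists after the data were seen. Some lists share members. For example, TNFAIP3, NFKBIA and BCL3 are in both NF-kB lists. LDHA and GAPDH are in both the reference list and the glycolysis and hypoxia list.

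The rule for named genes was also fixed in advance. It took the 10 highest and 10 lowest mean log2 ratios among features that passed and had the same sign on every array of the contrast (for the difference, at every time). Places left open were filled from features with an unadjusted p under 0.05 and the same sign, and the text says that these did not pass. For the slope it took 5 each way. RELA and RPS3 were always named, with up to 4 members of each list. Not every gene taken by the rule is printed in the text.

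Alternatives fixed in advance were no centring, scale or quantile normalization, values on at least 2 of the 3 arrays of each siRNA (8797 features), each of 10721 probes alone, robust moderation of variances, only the arrays of 1 siRNA in the fit, the time point as a block, array run as a covariate, a 2-fold size threshold, an estimated correlation in camera, fry of limma, and leaving out each array in turn. Removal of the medians of blocks of 100 neighbouring probe numbers, leaving out both 6 h arrays, and averaging only probes with values on all 6 arrays (7189 features) were added after the data were seen.

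The fits were tested on simulated data with 200 of the 7267 features changed in 20 simulations. For the p65 siRNA contrast, 27.8% of features with a log2 change of 0.5 and 96.8% of those with a change of 1 were recovered, and for the RPS3 siRNA contrast 30.6% and 95.3%. The difference recovered 6% and 71.9%, and the mean of all 6 arrays 75.3% and 99.6%. A slope of 0.2 per h was recovered in 43.3% and a slope of 0.4 in 97.7%. These shares depend on the number of features changed, and the simulated errors were independent between arrays and between genes. A shift of -0.3 put into the G2 and M phase list for RPS3 siRNA was found in 20 of 20 simulations, with 1 call among 440 tests of other lists. In the data, genes of a list can vary together, with an estimated correlation of 0.083 for this list. The simulations therefore give no rate of false list calls for these data.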

Results

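The arrays compared transcript levels in Jurkat cells after knockdown of p65, the NF-kB subunit encoded by RELA, or of RPS3, a protein of the small ribosomal subunit, each against nonspecific siRNA. NF-kB is a transcription factor held inactive by IkB proteins and released by signals such as T-cell receptor stimulation, and the series asks about RPS3 as a part of p65 complexes. There were 3 arrays per siRNA, 1 each at 1, 3 and 6 h of anti-CD3/CD28 stimulation, so a single time point had no replicate check. Of 15246 probes, 14423 had a value on the p65 siRNA array at 1 h, 13701 at 3 h and 12984 at 6 h; the RPS3 siRNA arrays had 13868, 14149 and 12946. The standard deviation of the log2 ratios ran from 0.26 on the RPS3 siRNA array at 3 h to 0.51 on the p65 siRNA array at 3 h. Log2 ratios are siRNA over control, the likely direction, with SD over the arrays of a group (n = 3 unless stated).

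The targeted transcripts were examined first. The RPS3 probe read -2.50, -2.53 and -1.44 on the RPS3 siRNA arrays at 1, 3 and 6 h, a mean of -2.16 ± 0.62 or 4.46-fold lower, with a limma adjusted p of 0.0993. On the p65 siRNA arrays it read 0.11, 0.01 and 1.11. Some probes with numbers close to its own were also low on the RPS3 siRNA arrays, as given at the end of the text. RELA averaged -0.49 ± 0.09 on the p65 siRNA arrays (adjusted p = 0.935) and -0.54 ± 0.15 on the RPS3 siRNA arrays (adjusted p = 0.306), so it was no lower with its own siRNA than with the other. The RELA probes disagreed: probe 15848_1 averaged -0.91 and -1.07 on the p65 and RPS3 siRNA arrays, and probe 28407_1 averaged -0.06 and -0.01. With each probe tested alone, RPS3 fell on the RPS3 siRNA arrays (adjusted p = 0.0439), and so did RELA probe 15848_1 (adjusted p = 0.0439). That RELA probe did not pass on the p65 siRNA arrays (adjusted p = 0.148). With the time point as a block RPS3 passed on the RPS3 siRNA arrays (limma adjusted p = 0.0019), but not with array run as a covariate (0.284). RPS3 also passed on the RPS3 siRNA arrays without the p65 siRNA 6 h array (mean -2.16, adjusted p = 0.0173) and without the RPS3 siRNA 6 h array (mean -2.52, adjusted p = 0.0276). It did not pass in the other 4 fits with 1 array left out, with an adjusted p of 0.335 and 0.221 without the p65 siRNA 1 h and 3 h arrays and of 0.795 and 0.413 without the RPS3 siRNA 1 h and 3 h arrays.

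**Figure D1:**
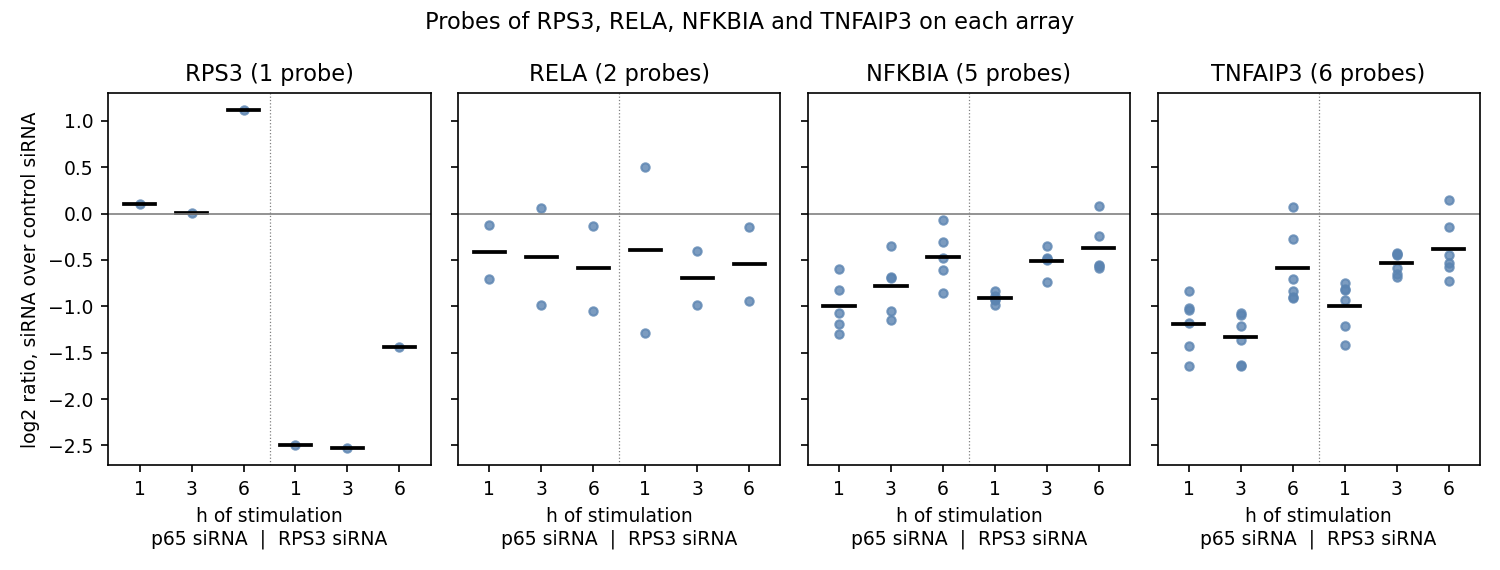
Log2 ratio of siRNA over control siRNA (vertical axis) for each probe of RPS3, RELA, NFKBIA and TNFAIP3 on the arrays at 1, 3 and 6 h of stimulation; points are probes and bars are their mean on an array. The RPS3 probe lay between -2.53 and -1.44 on the RPS3 siRNA arrays, and RELA was lower on the arrays of both siRNAs at 1 of its 2 probes.

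The first comparison asked which transcripts depend on p65 after stimulation. TNFAIP3, which encodes the NF-kB inhibitor A20, averaged -1.04 ± 0.40 on the p65 siRNA arrays, and NFKBIA, which encodes IkB-alpha, averaged -0.75 ± 0.27; both lay below 0 at all 3 times. SGK1, a serum- and glucocorticoid-regulated kinase, averaged -0.62 ± 0.18, and the mitotic kinesin CENPE -0.59 ± 0.25. Other low means belonged to ARAP2 (-0.91), INO80D (-0.85), CD2AP (-0.78), PARPBP (-0.71), DNAJC3 (-0.66) and ASPM (-0.53). The highest and lowest genes of a contrast are taken from those with 1 sign on every array and an unadjusted p under 0.05, so larger but more variable means are left out. Other examples from the gene lists need not meet that rule. Among the highest were CELA3A (0.63), GABBR1 (0.60), RGS4 (0.58), SSR4 (0.56) and CYP1B1 (0.54). FAM117B (0.52), the chemokine CXCL11 (0.50), the recombinase gene RAG1 (0.48 ± 0.09), RAD51B (0.46) and HUS1 (0.46) followed. Sizes depended on single arrays. Leaving out 1 array gave -1.30 to -0.49 for ARAP2, -1.09 to -0.36 for CD2AP, -0.97 to -0.33 for PARPBP and -0.86 to -0.41 for DNAJC3. For GABBR1 it gave 0.21 to 0.86, for RGS4 0.37 to 0.88, for CXCL11 0.21 to 0.65, for HUS1 0.20 to 0.64, for RAD51B 0.24 to 0.62 and for CYP1B1 0.36 to 0.72. FAM117B had no probe with values on all 6 arrays. The 3 probes of RGS4 disagreed: 1 of them, with a number close to that of the RPS3 probe, read -1.13, -1.09 and -0.34 on the RPS3 siRNA arrays. None of these genes passed: limma called 0 of 7267 features (lowest adjusted p = 0.587). Unadjusted, 360 had a p under 0.05, 197 higher and 163 lower, where 363 are expected by chance. This count depended on the fit: it was 750 with the time point as a block, 750 without both 6 h arrays and 202 without the p65 siRNA 3 h array. The balance of directions also turned over, with 265 higher and 485 lower without both 6 h arrays. Without the p65 siRNA 6 h array 142 were higher and 261 lower.

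As groups, the NF-kB and IkB family was lower on the p65 siRNA arrays, with a median of -0.28 and 11 of 13 members below 0 (adjusted p = 2.14e-07). This call was lost with adjusted p = 0.428 with an estimated correlation. Within the family 3 genes fell when adjusted over the list alone, TNFAIP3, NFKBIA and RELA, against 0 over all features, and BCL3 averaged -0.34 ± 0.10. RELA is the target of the p65 siRNA, so its own fall says nothing about genes that depend on p65. The family was not tested without it. The NF-kB target genes had 38 of 60 members below 0 and a median of -0.05 (adjusted p = 0.0099). With adjusted p = 0.434 with an estimated correlation they did not pass. In this list 2 genes, TNFAIP3 and NFKBIA, fell when adjusted over the list alone, and CD83, a surface marker of activated cells, averaged -0.47 ± 0.07.

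Higher on the p65 siRNA arrays were 6 lists, in which 0 members passed when adjusted over the list alone or over all features. Small ribosomal subunit proteins other than RPS3 had 12 of 13 above 0 and a median of 0.19 (adjusted p = 0.0048; adjusted p = 0.541 with an estimated correlation). All 11 large ribosomal subunit proteins tested, of 47 in the list, lay above 0, such as RPLP1 at 0.36 ± 0.08. Their median was 0.11 (adjusted p = 0.0315, and adjusted p = 0.428 with an estimated correlation). Glycolysis and hypoxia genes had 19 of 25 above 0, among them LDHA at 0.30 ± 0.11. Their median was 0.15 (adjusted p = 0.0092; adjusted p = 0.544 with an estimated correlation). Oxidative phosphorylation genes had 15 of 16 above 0 and a median of 0.13 (adjusted p = 0.0165; adjusted p = 0.428 with an estimated correlation). Translation factors had 20 of 23 above 0 and a median of 0.11 (adjusted p = 0.0304; adjusted p = 0.544 with an estimated correlation). Reference genes, transcripts often used for normalization, had 10 of 12 above 0 and a median of 0.20 (adjusted p = 0.0304; adjusted p = 0.544 with an estimated correlation), and GAPDH averaged 0.41 ± 0.54 (0.11 to 0.63 with 1 array left out). LDHA and GAPDH are in both the reference and the glycolysis list, so these calls are not independent. Markers of other cell lineages did not pass (adjusted p = 0.0658). Their median was 0.29 on the p65 siRNA array at 3 h, against -0.0045 at 1 h and 0.03 at 6 h.

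Leaving out 1 array gave medians of 0.03 to 0.22 for glycolysis and hypoxia genes, 0.03 to 0.17 for translation factors and 0.07 to 0.26 for reference genes. It gave 0.11 to 0.34 for the small and 0.10 to 0.17 for the large ribosomal subunit proteins, and -0.07 to -0.02 for NF-kB target genes, which had adjusted p = 0.342 without the 1 h array. Against 8 lists in all, 1 list passed without the p65 siRNA 1 h array, the NF-kB and IkB family (adjusted p = 0.0031), and 15 lists passed without the 3 h array. Without the 6 h array 4 passed. Glycolysis and hypoxia genes (adjusted p = 0.742), reference genes (adjusted p = 0.588), translation factors (adjusted p = 0.224) and NF-kB target genes (adjusted p = 0.0666) were then lost.

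The second comparison asked the same of RPS3. HSPA5, the endoplasmic reticulum chaperone BiP, averaged -0.82 ± 0.09 on the RPS3 siRNA arrays. Of genes with roles in mitosis, DEPDC1 averaged -0.86 ± 0.17, CENPE -0.84 ± 0.22, KIF14 -0.76 ± 0.22 and CDCA2 -0.74 ± 0.19. BHLHE40 (-0.97 ± 0.54), SGK1 (-0.77 ± 0.19) and ID1 (-0.72 ± 0.26), the last an inhibitor of basic helix-loop-helix factors, were also low on all 3 arrays. The highest means under the same rule were those of OGN (0.75), the potassium channel gene KCNN3 (0.74, resting on a probe blank on 4 of 6 arrays), PGGHG (0.68), SLA (0.65) and the Ras activator RASGRP1 (0.65 ± 0.25). GPCPD1 (0.64), ACAP1 (0.57), KLHL18 (0.57), the initiation factor EIF5 (0.56 ± 0.26) and ACKR3 (0.56 ± 0.20) followed. Leaving out 1 array gave 0.21 to 0.84 for KLHL18, 0.23 to 0.77 for ACAP1, 0.33 to 0.89 for SLA, 0.42 to 0.87 for PGGHG and 0.42 to 1.05 for KCNN3. The only KCNN3 probe with values on all 6 arrays averaged 0.07, and GPCPD1 had no such probe. None passed: limma called 0 of 7267 features (lowest adjusted p = 0.0880). At an unadjusted p under 0.05 there were 636, 290 higher and 346 lower, and with the time point as a block 1152, 594 higher and 558 lower. The time point as a block gave 3 lower calls, leaving out both 6 h arrays gave 3, quantile normalization 2 and single probes 7. Without the p65 siRNA 6 h array there were 2 lower calls, and without the RPS3 siRNA 6 h array also 2.

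The G2 and M phase list was lower on the RPS3 siRNA arrays, with 31 of 31 members below 0 on average and a median of -0.37 (adjusted p = 2.92e-16). The call was lost with adjusted p = 0.146 with an estimated correlation. On all 3 arrays, 21 members lay below 0. Adjusted over the list alone, 12 members fell, against 0 over all features. They were CENPE, KIF14, CCNB1 (-0.70 ± 0.32), CENPF (-0.59 ± 0.21), CENPA, KIF11, CDK1 (-0.57), UBE2C, BUB1, PLK1 (-0.63), KIF23 and HMMR. CCNB1 encodes cyclin B1 and CDK1 its kinase, and PLK1 and BUB1 encode kinases of mitosis. The list's median was -0.43, -0.30 and -0.36 at 1, 3 and 6 h, and it passed without any 1 of the 6 arrays. Leaving out a p65 siRNA array cannot change this median. Without 1 RPS3 siRNA array it ran from -0.36 to -0.35. Within the runs, the median difference of RPS3 from p65 siRNA was -0.41 in run 1 (1 array each) and -0.27 in run 2 (2 arrays each). In each run the times of the siRNAs also differed.

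**Figure D2:**
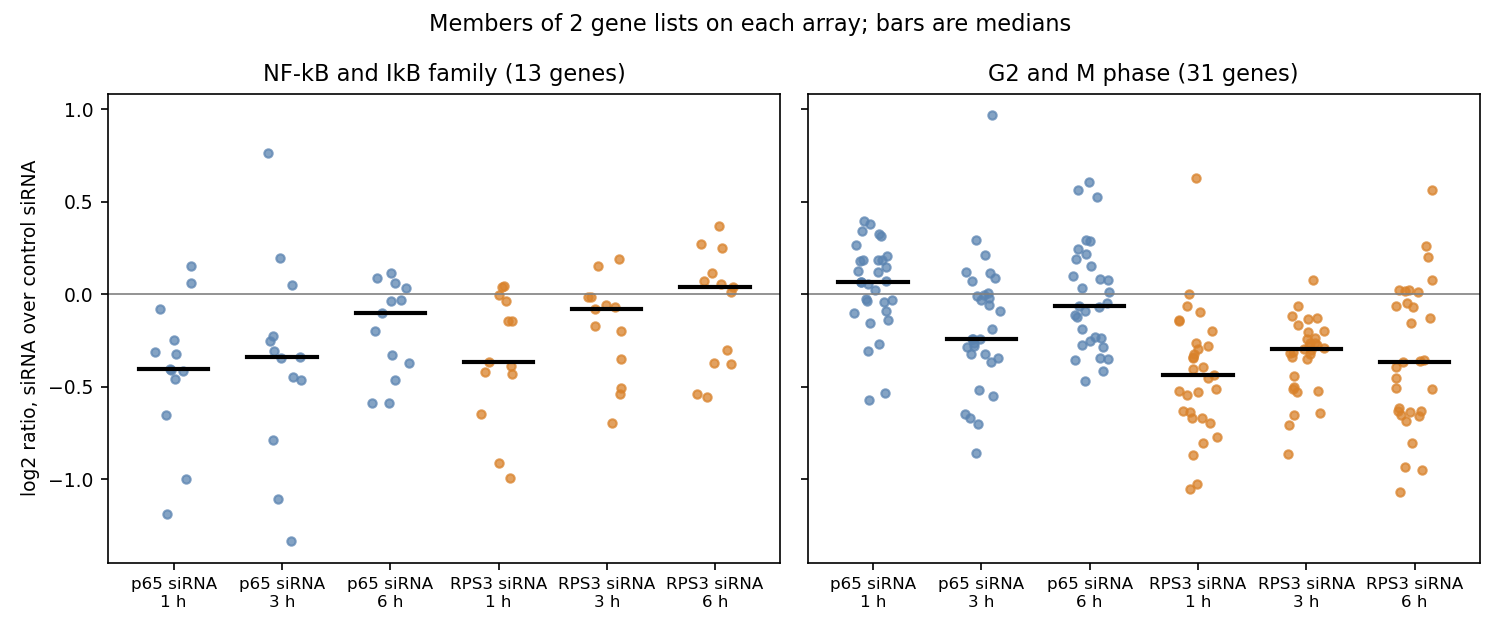
Log2 ratio of siRNA over control siRNA (vertical axis) for the measured members of the NF-kB and IkB family (13 genes, left) and of the G2 and M phase list (31 genes, right) on each array; points are genes and bars are medians. G2 and M phase medians lay between -0.43 and -0.30 on the RPS3 siRNA arrays and between -0.24 and 0.07 on the p65 siRNA arrays.

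Another 3 lists were lower with RPS3 siRNA. The NF-kB and IkB family had 10 of 13 below 0 and a median of -0.09 (adjusted p = 0.0169; adjusted p = 0.630 with an estimated correlation). The median rested on single arrays and ran from -0.22 to -0.024 when 1 was left out. When adjusted over the list alone 4 genes fell, TNFAIP3 (-0.64 ± 0.32), NFKBIA (-0.60 ± 0.28), RELA and the IkB-like BCL3 (-0.46 ± 0.25). Genes of the unfolded protein and amino acid stress response had 18 of 25 below 0 and a median of -0.12 (adjusted p = 0.0236; adjusted p = 0.630 with an estimated correlation). They included HSPA5, XBP1 (-0.44 ± 0.07) and DNAJC3 (-0.54 ± 0.20), and 2 fell when adjusted over the list alone. Immediate-early activation genes had 21 of 30 below 0 and a median of -0.08 (adjusted p = 0.0232; adjusted p = 0.630 with an estimated correlation). Examples were DUSP5 (-0.55 ± 0.20), IER5 (-0.40 ± 0.15), BTG1 (-0.41 ± 0.18) and MCL1 (-0.33 ± 0.14), and 1 gene fell when adjusted over the list alone.

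Higher with RPS3 siRNA was ribosome assembly and nucleolus, with 15 of 17 above 0 and a median of 0.14 (adjusted p = 0.0169; adjusted p = 0.630 with an estimated correlation). POLR1C averaged 0.46 ± 0.41, NHP2 0.37 ± 0.32 and PPAN 0.34 ± 0.13. With 1 array left out POLR1C ran from 0.24 to 0.65 and NHP2 from 0.19 to 0.50. T cell receptor complex and signalling had 25 of 31 above 0 and a median of 0.09 (adjusted p = 0.0232; adjusted p = 0.630 with an estimated correlation). CD2 averaged 0.46 ± 0.10, RAG1 0.38 ± 0.12 and CD6 0.34 ± 0.28 (0.17 to 0.45 with 1 array left out). In both lists 0 members passed when adjusted over the list alone. Of the 6 lists, only G2 and M phase passed without the RPS3 siRNA 3 h array. The medians of the immediate-early list (-0.13 to -0.012), ribosome assembly (0.12 to 0.34) and the T cell receptor list (0.0095 to 0.17) also varied when 1 array was left out. Without the RPS3 siRNA 3 h array the adjusted p was 0.0568 for the NF-kB and IkB family, 0.184 for the stress response, 0.110 for ribosome assembly, and 0.0954 for the immediate-early and the T cell receptor lists. Without the 1 h array the family (adjusted p = 0.131) and the stress response list (adjusted p = 0.228) were lost. Without the 6 h array the immediate-early list (adjusted p = 0.717), ribosome assembly (adjusted p = 0.327) and the T cell receptor list (adjusted p = 0.717) were lost.

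The direct contrast, RPS3 siRNA minus p65 siRNA, asked where the knockdowns differed. The RPS3 transcript differed by -2.57 ± 0.03 over the 3 times (adjusted p = 0.511) and HSPA5 by -0.84 ± 0.14. ID1 differed by -0.78 ± 0.05 and CCNB1 by -0.67 ± 0.14. IFIT1 (-0.77), NOTCH3 (-0.77), CTSG (-0.76), the mitotic kinase gene PBK (-0.72) and BHLHE40 (-0.66) were also lower with RPS3 siRNA. Higher with RPS3 siRNA were NVL (0.83), OGN (0.79), TBC1D4 (0.79), CUTALP (0.78) and EIF5 (0.75). DMD (0.70 ± 0.06), RASGRP1 (0.65), DTNB (0.63 ± 0.04), SNX14 (0.62) and AMPD3 (0.61) followed, and RELA differed by -0.05 ± 0.15. None passed: limma called 0 of 7267 features (lowest adjusted p = 0.511). Unadjusted, 185 had a p under 0.05, 68 higher and 117 lower, where 363 are expected by chance. That fit does not match the arrays by time. With the time point as a block 451 features had an unadjusted p under 0.05, and 2 lower features passed, RPS3 (adjusted p = 0.0055) and an unnamed probe. RPS3 also passed without both 6 h arrays (adjusted p = 0.0154). Sizes depended on single arrays: leaving out 1 array gave 0.38 to 1.11 for NVL, 0.45 to 1.05 for CUTALP and -1.03 to -0.44 for IFIT1.

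Of the lists, 9 were lower with RPS3 siRNA than with p65 siRNA and 2 higher. G2 and M phase had 30 of 31 members lower, with a median of -0.29 (adjusted p = 5.06e-12; adjusted p = 0.218 with an estimated correlation). CDK1 differed by -0.62 ± 0.16 and KIF14 by -0.53 ± 0.31. Small ribosomal subunit proteins had 11 of 13 lower and a median of -0.34 (adjusted p = 4.8e-05; adjusted p = 0.347 with an estimated correlation). RPS29 (-0.62 ± 0.11), RPS9 (-0.53 ± 0.12) and RPS16 (-0.45 ± 0.09) were lower, while RPS15A was 0.51 ± 0.23 higher. The large subunit had 10 of 11 lower and a median of -0.27 (adjusted p = 0.0014; adjusted p = 0.218 with an estimated correlation). Glycolysis and hypoxia genes, such as PGAM1 at -0.49 ± 0.08, had a median of -0.16 (adjusted p = 8.46e-05; adjusted p = 0.417 with an estimated correlation). The stress response list had a median of -0.16 (adjusted p = 0.0014; adjusted p = 0.457 with an estimated correlation). XBP1, a transcription factor of that response, differed by -0.44 ± 0.17 and MANF by -0.44 ± 0.09. Cholesterol and fatty acid synthesis had a median of -0.23 (adjusted p = 0.0022; adjusted p = 0.347 with an estimated correlation), with SCD and INSIG1 both at -0.38. S phase and DNA replication had a median of -0.12 (adjusted p = 0.0034; adjusted p = 0.457 with an estimated correlation), with TK1 at -0.53 ± 0.16 and FEN1 at -0.46 ± 0.16. Oxidative phosphorylation had a median of -0.16 (adjusted p = 0.0051; adjusted p = 0.241 with an estimated correlation), with UQCRB at -0.42 ± 0.04.

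Reference genes were lower by the same contrast, at a median of -0.15 (adjusted p = 0.0483; adjusted p = 0.457 with an estimated correlation). T cell receptor complex and signalling was higher, at a median of 0.10 (adjusted p = 0.0034; adjusted p = 0.457 with an estimated correlation). CD2 differed by 0.54 ± 0.16 and the kinase gene ZAP70 by 0.52 ± 0.14. Ribosome assembly and nucleolus had a median of 0.16 (adjusted p = 0.0345; adjusted p = 0.457 with an estimated correlation). Adjusted over the list alone, 1 member of the stress response list passed and 0 of the others. The NF-kB and IkB family (median 0.17, adjusted p = 0.0734) was not shown to differ between the siRNAs, nor were the NF-kB target genes (adjusted p = 0.623), whose median was -0.012 and mean 0.02.

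The sizes of these differences depended on single arrays. Among genes, the difference with 1 left out ran from -0.84 to -0.37 for RPS29, -0.76 to -0.35 for TK1, -0.62 to -0.26 for FEN1 and -0.58 to -0.24 for UQCRB. It ran from -0.52 to -0.22 for SCD, -0.46 to -0.25 for INSIG1 and 0.25 to 0.77 for ZAP70. With 1 left out the median ran from -0.27 to -0.016 for reference genes, so it nearly vanished, and from 0.05 to 0.28 for ribosome assembly. It ran from -0.30 to -0.12 for the cholesterol list, -0.28 to -0.12 for glycolysis, -0.32 to -0.14 for the large ribosomal subunit and -0.25 to -0.13 for oxidative phosphorylation. The S phase list ran from -0.20 to -0.07, the stress response list from -0.23 to -0.10 and the T cell receptor list from 0.05 to 0.18. In this contrast only G2 and M phase and both ribosomal protein lists passed without any 1 array. The cholesterol (adjusted p = 0.0950), oxidative phosphorylation (0.0913) and reference (0.132) lists were lost without the p65 siRNA 1 h array. Ribosome assembly (0.390) and the T cell receptor list (0.125) were lost without the p65 siRNA 3 h array. Without the p65 siRNA 6 h array it was the glycolysis (0.121), reference (0.602), S phase (0.189) and stress response (0.185) lists. Without the RPS3 siRNA 1 h array the reference (0.509), S phase (0.0726) and stress response (0.0559) lists were lost. Without the RPS3 siRNA 3 h array it was the reference (0.204), ribosome assembly (0.148) and S phase (0.0528) lists, and without the 6 h array ribosome assembly (0.552) and the T cell receptor list (0.377).

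Over all 6 arrays, the transcripts low with both siRNAs and of 1 sign on every array were led by TNFAIP3 (-0.84 ± 0.39, n = 6), CENPE (-0.72 ± 0.25), INO80D (-0.70), SGK1 (-0.70 ± 0.18) and NFKBIA (-0.67 ± 0.26), each below 0 on 6 of 6 arrays. DEPDC1 (-0.64), BHLHE40 (-0.64), PARPBP (-0.63), the spindle protein gene ASPM (-0.62 ± 0.26) and DNAJC3 (-0.60) followed. SSR4 (0.52), GABBR1 (0.49), BET1L (0.47), TMEM203 (0.46 ± 0.11) and CDC123 (0.45) were above 0 on 6 of 6 arrays, as were KLHL18 (0.43), TTBK2 (0.43), RAG1 (0.43 ± 0.11), NSF (0.43) and POLR1C (0.42). With 1 array left out NSF ran from 0.24 to 0.54, KLHL18 from 0.26 to 0.57 and GABBR1 from 0.30 to 0.62. None passed: limma called 0 of 7267 features (lowest adjusted p = 0.0986, for SGK1 among named genes). Of all features 794 had an unadjusted p under 0.05, 421 higher and 373 lower, and with the time point as a block 1338. Tested as single probes, 20 lower probes passed. Quantile normalization gave 7 lower and 1 higher calls, and scale normalization and leaving out both 6 h arrays 1 lower call each.

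Over all 6 arrays 5 lists passed. G2 and M phase was lower, with a median of -0.21 (adjusted p = 7.75e-10; adjusted p = 0.354 with an estimated correlation). The NF-kB and IkB family was lower, with a median of -0.11 (adjusted p = 1.45e-05; adjusted p = 0.414 with an estimated correlation). NF-kB target genes had a median of -0.06 (adjusted p = 0.0254; adjusted p = 0.681 with an estimated correlation). Immediate-early activation genes had a median of -0.04 (adjusted p = 0.0254; adjusted p = 0.804 with an estimated correlation). Translation factors were higher, with a median of 0.12 (adjusted p = 0.0183; adjusted p = 0.804 with an estimated correlation). The medians ran, with 1 array left out, from -0.067 to -0.0010 for immediate-early genes, so that theirs nearly vanished, and from -0.08 to -0.03 for NF-kB target genes. They ran from -0.23 to -0.14 for G2 and M phase and from -0.21 to -0.09 for the NF-kB and IkB family. Adjusted over the list alone, 3, 4, 4 and 2 members of the lower lists fell and 0 translation factors passed. Without the p65 siRNA 1 h array only the G2 and M phase list and the NF-kB and IkB family passed. NF-kB target genes and translation factors then had an adjusted p of 0.315 and immediate-early genes of 0.103. Without the RPS3 siRNA 6 h array the adjusted p was 0.258 for NF-kB target genes, 0.077 for translation factors and 0.327 for immediate-early genes. Immediate-early genes were also lost without the p65 siRNA 6 h array (adjusted p = 0.254). With block medians removed, NF-kB target genes (adjusted p = 0.0724) and immediate-early genes were lost. Without both 6 h arrays, NF-kB target genes (median -0.014, adjusted p = 0.336), immediate-early genes and translation factors were lost.

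Another 8 lists passed in none of the 5 contrasts, and the lowest adjusted p of each follows. With p65 siRNA it was 0.0605 for the proteasome (median 0.10), 0.0658 for markers of other cell lineages (0.13) and 0.593 for p53 target genes (-0.01). It was also lowest with p65 siRNA for heat shock proteins (0.734, median 0.08), apoptosis regulators (0.734, median -0.016) and interferon-stimulated genes (0.739, median 0.08). It was 0.260 for T cell cytokines and activation markers, from a slope of -0.011 per h, and 0.295 for RNA interference machinery, from a difference of 0.07. FAS, a death receptor, averaged -0.36 ± 0.36 with p65 siRNA and -0.50 ± 0.24 with RPS3 siRNA. The activation marker TNFRSF9 averaged -0.43 ± 0.22 with RPS3 siRNA, and the interferon-induced IFIT1 0.52 ± 0.61 with p65 siRNA. With 1 array left out IFIT1 ran from 0.19 to 0.78 and FAS with p65 siRNA from -0.56 to -0.22, and the complete probe of IFIT1 averaged 0.25. The median, mean and test of the apoptosis list differed in sign with p65 siRNA, as did those of the heat shock, interferon, p53 and reference lists with RPS3 siRNA.

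**Figure D3:**
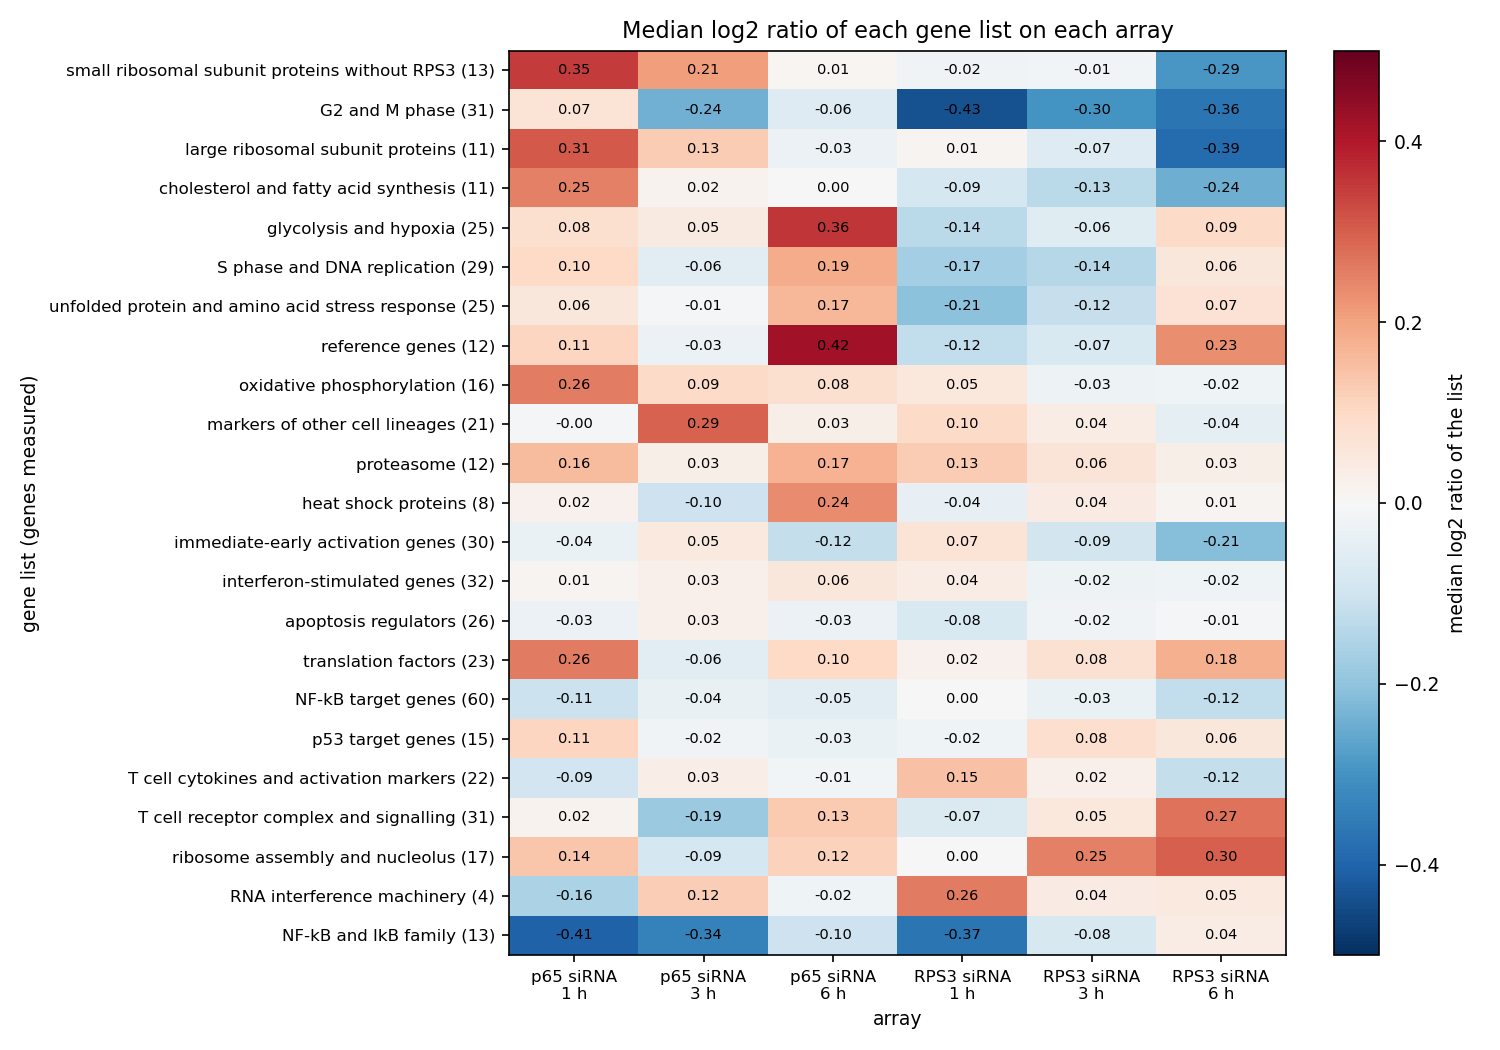
Median log2 ratio of siRNA over control siRNA for each of 23 gene lists (vertical axis, with the number of genes measured) on each of the 6 arrays (horizontal axis), as colour and number. The NF-kB and IkB family ran from -0.41 on the p65 siRNA array at 1 h to 0.04 on the RPS3 siRNA array at 6 h, and reference genes were highest, at 0.42 and 0.23, on the 6 h arrays.

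Time of stimulation was examined as the slope of the log2 ratio. Among named genes with an unadjusted p under 0.05, the highest slopes were those of SRSF4 (0.58 per h), the endoplasmic reticulum receptor gene KDELR1 (0.52), OXSR1 (0.51), MATR3 (0.49) and ZNF257 (0.49). The lowest were those of FAM120A (-0.27), EAF2 (-0.25), P2RY10 (-0.22), TPMT (-0.18) and NEK2 (-0.18). The slopes of FAM120A and NEK2 partly reflect which probes were blank: the complete probe of FAM120A gave -0.09, and NEK2 had no probe with values on all 6 arrays. With 1 array left out these slopes ran from -0.40 to -0.16 for FAM120A, -0.36 to -0.14 for P2RY10 and -0.29 to -0.13 for NEK2. They ran from 0.28 to 0.68 for OXSR1 and 0.29 to 0.66 for ZNF257. KDELR1 read -0.80, -0.77 and 1.65 on the p65 siRNA arrays at 1, 3 and 6 h, and -0.99, -0.59 and 1.53 on the RPS3 siRNA arrays. None passed: limma called 0 of 7267 features (lowest adjusted p = 0.0866). At an unadjusted p under 0.05 there were 1700, 1032 with a slope above 0 and 668 below, where 363 are expected by chance. That number holds for independent arrays. The 6 h arrays of the 2 siRNAs correlated with r = 0.686 and may share a control RNA, so the excess need not come from time. The calls at an adjusted p under 0.05, 0 in the full fit, depended on single arrays. With the p65 siRNA 1 h array left out 497 features passed as rising and 110 as falling. With the p65 siRNA 3 h array left out 261 passed as rising and 12 as falling. Quantile normalization gave 1 rising call.

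Relations between the siRNAs were described across features, which are not independent replicates. The mean log2 ratios of the p65 and RPS3 siRNA arrays correlated with Pearson r = 0.401 and Spearman rho = 0.377, and 62.3% of features had the same sign. If both siRNAs were compared with 1 control RNA per time, simulated groups with no effect gave r = 0.503, rho = 0.462 and 66.7% of the same sign; with separate controls they gave r near 0 (-0.00061). The covariance was 0.0155, against a simulated 0.0177 with a shared control. The simulation gave control and siRNA samples equal variance, and its r depends on that. The labels do not say whether the control RNA was shared, so part of the relation can come from it. How large a part was not settled. As labelled, pairs of different times (r = 0.480 and 0.440) correlated above the time-matched pairs at 1 h (0.163) and 3 h (0.178). Each comparison called 0 features, so an overlap of calls could not be examined. At an unadjusted p under 0.05, 52 features were lower with both siRNAs, 36 higher with both and 1 opposite, against 7.76 lower and 7.86 higher for independent lists and 58.6 each with a shared control. Without the p65 siRNA 6 h array r was 0.181 and without the RPS3 siRNA 1 h array 0.243. With another array left out it was 0.372 to 0.419, and without both 6 h arrays r = 0.4995.

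Array by array, the 6 h arrays of the 2 siRNAs correlated most (r = 0.686), then p65 siRNA at 3 h with RPS3 siRNA at 1 h (r = 0.480) and p65 siRNA at 1 h with RPS3 siRNA at 3 h (r = 0.440). The time-matched arrays at 1 h (r = 0.163) and 3 h (r = 0.178) correlated less. Arrays of 1 siRNA had a mean r of 0.0559, so the 3 arrays of a group were far from replicates of each other. By run, the 6 pairs within run 2 had a mean r of 0.137, the pair in run 1 had r = 0.440, and the 8 pairs between runs had a mean r of 0.052.

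**Figure D4:**
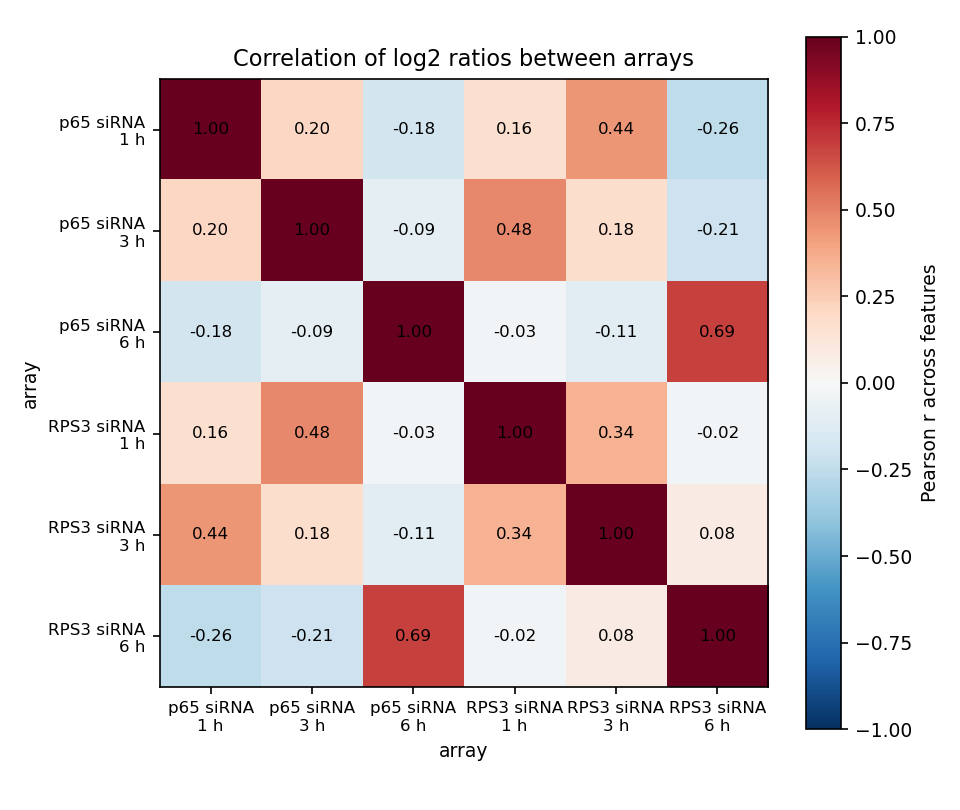
Pearson correlation of log2 ratios across 7267 features for each pair of the 6 arrays, as colour and number, with siRNA and h of stimulation on both axes. The highest value off the diagonal, 0.69, joins the 6 h arrays, and values between arrays of 1 siRNA lie between -0.18 and 0.34.

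By size alone, 8 features were at least 1.5-fold lower on all 3 RPS3 siRNA arrays, among them RPS3, HSPA5, CENPE and DEPDC1, and 3 on all 3 p65 siRNA arrays, of which TNFAIP3 was the named 1. Shuffling features within arrays 100 times gave a mean of 0.1 and 0.06, and 0 features were 1.5-fold higher on all 3 arrays of either siRNA. Most of the other features were unnamed probes. These counts rest on each array: with p65 siRNA, 9 were lower without the 1 h, 8 without the 3 h and 62 without the 6 h array, and with RPS3 siRNA 20, 26 and 35. Higher features numbered 13, 2 and 1 with p65 siRNA and 7, 22 and 2 with RPS3 siRNA when the same arrays were left out. Because the shuffle breaks every link between arrays, dye effects of single probes or unequal spread of probes could also exceed it.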

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

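The tests of slopes on gene lists and all tests of explanations given here were chosen after the results were seen, except the tests of a shared control RNA and of array run for the G2 and M phase list. By the test of the slope with both siRNAs in the fit, log2 ratios changed over the 3 stimulation times for 4 gene lists. Both 6 h arrays lay in run 2 and correlated with r = 0.686. A control RNA shared at 6 h, or a technical effect common to these arrays, cannot be told apart from an effect of time. Glycolysis and hypoxia genes had a median slope of 0.044 per h over 25 genes, with 18 above 0, such as ENO1 (0.36) and GAPDH (0.20). T cell receptor complex and signalling genes had 0.037 over 31 genes, with 22 above 0, such as ZAP70 (0.18) and LCK (0.15). Immediate-early activation genes had -0.033 over 30 genes, with 20 below 0, and small ribosomal subunit proteins without RPS3 had -0.051 over 13 genes, with 11 below 0. Each had an adjusted p of 0.0356, and all 4 were lost with adjusted p = 0.858 with an estimated correlation. Without the p65 siRNA 3 h, p65 siRNA 6 h or RPS3 siRNA 6 h array 0 lists passed, without the RPS3 siRNA 1 h array 2, and without the p65 siRNA 1 h array 7.

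Correlations between arrays did not follow the time-matched pairs. Array run as the whole cause is argued against by the pair of p65 siRNA at 3 h and RPS3 siRNA at 6 h, which share run 2 and correlated with r = -0.207, below the highest pair from different runs (r = 0.345). An exchange of the 1 h and 3 h labels for 1 siRNA would give the 2 crossed pairs seen here, of which the lower had r = 0.440 against 0.178 for the higher time-matched early pair. It cannot be told apart from an effect of run, because both crossed pairs lie within a run and both time-matched early pairs between runs. Effects of single probes shared by pairs of arrays are a candidate explanation for part of the pattern: deviations of 5449 probes from the means of their 1917 genes correlated with at least r = 0.384 in the 3 strong pairs, against 0.207 for the higher time-matched early pair.

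The NF-kB and IkB family was lower on average with both siRNAs, a call lost with an estimated correlation (adjusted p = 0.428 for p65 and adjusted p = 0.630 for RPS3 siRNA), and for RPS3 siRNA also without the 1 h or 3 h array, with a median of 0.037 on the 6 h array. No test argued against a technical cause. Dye bias stays open because every knockdown sample was in Cy5, and the family's difference between siRNAs, which such a bias would leave at 0, had an adjusted p of 0.0734. A control RNA shared by both siRNAs at each time stays open too: over the 13 members the time-matched pairs had a mean r of 0.736, which was 0.207 above that of the other pairs, with a bootstrap SD of 0.113 over the members. A shared dependence of these genes on p65 and RPS3 was not tested, as the design has no array that separates it from these.

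The G2 and M phase list was lower on the RPS3 siRNA arrays, a call lost with adjusted p = 0.146 with an estimated correlation; the difference from p65 siRNA was lost with adjusted p = 0.218 in the same way and adjusted p = 0.132 with fry. Dye bias alone would give both siRNAs the same list median, as their arrays carry the same dyes. The median difference from the p65 siRNA arrays was -0.287, with a bootstrap SE of 0.0349 over member genes, not over arrays. Of all splits of the arrays into 3 and 3, the real 1 gave the largest median in size. Grouping p65 siRNA at 1 and 6 h with RPS3 siRNA at 3 h, against the rest, gave 0.244, the largest of the others. The remaining splits gave 0.02 to 0.17. Each split other than the real 1 mixes the siRNAs unevenly, so it also holds part of any difference between them. With so few splits, and 1 of them close in size, the difference from p65 siRNA argues only weakly against dye bias alone. Array run as the whole cause would leave no difference within a run. The differences within run 1 (-0.407) and run 2 (-0.275) argue against it only weakly, because siRNA was mixed with time within runs. Run 1 set p65 siRNA at 1 h against RPS3 siRNA at 3 h, with 1 array each and so no spread between arrays. Run 2 set p65 siRNA at 3 and 6 h against RPS3 siRNA at 1 and 6 h. Fewer dividing cells with RPS3 siRNA may account for the lower G2 and M phase list, which was not decided: the S phase and DNA replication list had a median of -0.062 on the RPS3 siRNA arrays with an adjusted p of 0.0961. By camera that list was lower than with p65 siRNA, at a median difference of -0.12 (adjusted p = 0.0034). With an estimated correlation this call was lost (adjusted p = 0.457). Part of the difference lay on the p65 siRNA arrays, where the S phase median was 0.07. By time, the median difference of the G2 and M phase list was -0.57 at 1 h, -0.14 at 3 h and -0.37 at 6 h, with 28, 24 and 30 of 31 members lower.

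The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For RPS3 siRNA minus p65 siRNA, the real split gave 0 features by limma, and the highest other split also 0, so 10 of 10 gave as many. At an unadjusted p under 0.05 the real split gave 185 features and the highest other 1095, from p65 siRNA at 1 and 3 h with RPS3 siRNA at 1 h against the rest, and 6 of 10 gave as many. The 4 splits with both 6 h arrays on 1 side gave 769 to 1095 and the others at most 342, so the count is larger where the 6 h arrays stand together. These counts are from fits without the time block. The real split gave 11 lists and the highest other also 11, from p65 siRNA at 1 and 6 h with RPS3 siRNA at 6 h, so 2 of 10 gave as many.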

How the results depend on the processing

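Removal of block medians, leaving out both 6 h arrays and averaging only complete probes were chosen after the data were seen; the other settings were fixed before. Over all settings, 330 of 413 lead values kept their direction and side of the threshold, or for counts stayed within 1.5 times, though sizes among them could change. Of the others 75 counts moved by over 1.5 times and 8 values of target genes newly passed; none reversed. Of values for named genes, 1430 of 1457 again did not pass and 27 newly passed. No named gene passed in the main fit, so this agreement says little about the genes. Many lead values were likewise counts of 0, or target genes that did not pass, in the main fit. Their agreement therefore says little too. Of named lists 465 of 618 kept their call and 153 lost it. Neither values as deposited, without centring, nor averaging only probes with values on all 6 arrays moved a lead value. The cause of the changes below was not tested. Signal over background is unknown, so dim probes could not be set apart.

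Lower calls for RPS3 siRNA, 0 in the report, numbered 2 with quantile normalization, 7 with single probes, 3 with the time block, 3 with block medians removed and 3 without the 6 h arrays (0 to 2 leaving out 1 array). For the difference, lower calls numbered 1, 2 and 1 with quantile normalization, the time block and no 6 h arrays. Over all 6 arrays there was 1 higher call with quantile normalization. Lower calls were 1 with scale normalization, 7 with quantile normalization, 20 with single probes and 1 without the 6 h arrays. For slopes, quantile normalization gave 1 rising call, and leaving out 1 array gave 0 to 497 rising and 0 to 110 falling. On the RPS3 siRNA arrays, RELA at probe 15848_1 was -1.07 (adjusted p = 0.0439; gene mean -0.54). RPS3 there was -2.61 with quantile normalization, -2.16 as a probe alone or with the time block, -2.12 with block medians removed and -2.52 without the 6 h arrays, and all of these passed. Leaving out 1 array gave -2.52 to -1.97.

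Lists for p65 siRNA (8) numbered 5 with values on at least 2 of 3 arrays, 0 with an estimated correlation, 0 with fry, 4 without the 6 h arrays and 1 to 15 leaving out 1 array. For RPS3 siRNA (6) they numbered 0 with an estimated correlation, 1 with fry and 1 to 6 leaving out 1 array. For the difference (11) they numbered 0 with an estimated correlation, 0 with fry and 8 to 10 leaving out 1 array. Over all 6 arrays (5) they numbered 0 with an estimated correlation, 3 with fry, 3 with block medians removed, 2 without the 6 h arrays and 2 to 7 leaving out 1 array. For slopes (4) they numbered 1 with quantile normalization, 0 with an estimated correlation, 0 with fry and 0 to 7 leaving out 1 array.

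Features 1.5-fold lower on all p65 siRNA arrays (3) numbered 27 with values on at least 2 of 3 arrays, 17 as single probes, 1 at 2-fold, 62 without 6 h and 8 to 62 leaving out 1 array. Higher features (0) numbered 4 with values on at least 2 of 3 arrays, 1 without 6 h and 1 to 13 leaving out 1 array. On RPS3 siRNA arrays lower features (8) numbered 13 with scale normalization, 16 with quantile normalization, 14 with values on at least 2 of 3 arrays, 22 as single probes, 2 at 2-fold, 35 without 6 h and 20 to 35 leaving out 1 array. Higher features (0) numbered 1, 2, 11 and 1 with the first 4 of these settings, 2 without 6 h and 2 to 22 leaving out 1 array. Counts with fewer arrays or with blanks allowed need fewer values to agree, which raises them by construction.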

Other observations

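The probes and tests in this part were chosen after the values were seen. NF-kB feedback genes and a surface marker were low at several probes with both siRNAs. All 5 NFKBIA probes and all 6 TNFAIP3 probes had means below 0 with each siRNA, from -0.98 to -0.42 and from -1.11 to -0.97 with p65 siRNA, and from -0.66 to -0.47 and from -0.71 to -0.59 with RPS3 siRNA. CD83 probe 17066_1 averaged -0.95 with p65 siRNA and -1.13 with RPS3 siRNA, and probe 19239_1 -0.85 and -1.01, while probe 30249_1 averaged -0.07 and 0.03. SPI1, a transcription factor of myeloid and B cells, averaged -0.91 and -1.09 at probe 24559_1, with its other probes nearer 0. At 6 h the probes of a gene disagreed: TNFAIP3 probe 35299_1 read -1.64 and -1.63 on the p65 siRNA arrays at 1 and 3 h and 0.07 at 6 h, and NFKBIA probe 34886_1 read -1.30, -1.05 and -0.07.

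Among probes without a symbol, 35578_1 followed the RPS3 probe, with -2.53, -2.10 and -1.50 on the RPS3 siRNA arrays and 0.20, -0.11 and 0.95 on the p65 siRNA arrays. Probe 35542_1 read -1.71, -1.34 and -0.70 on the RPS3 siRNA arrays. Their adjusted p was 0.0880 and 0.306 by limma on the RPS3 siRNA arrays. Their sequences were not used here.

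Gene means and probe deviations behaved differently between pairs of arrays. For RPS3 siRNA at 1 and 3 h, means of 1917 genes correlated with r = 0.539 and the deviations of their probes with r = 0.188, while for the 6 h arrays of the 2 siRNAs these were 0.762 and 0.651. Medians of blocks of 100 neighbouring probe numbers reached 0.42 on the p65 siRNA array at 3 h and -0.43 on the RPS3 siRNA array at 6 h. With these medians removed, the 3 strong pairs of arrays still correlated with r = 0.418, 0.463 and 0.680.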
